A study of Bos taurus with 48 samples.

How the data were processed

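DNA methylation was measured by whole-genome bisulfite sequencing in 6 organs of 8 male dairy calves, which gave 48 libraries. The calves were grouped by the embryo origin in the labels, 4 IVP and 4 MOET, and are named as in the authors' column names (MOET_3213). The same calf number in different organs was read as the same animal. Per the labels, a company extracted the DNA, made bisulfite libraries, sequenced paired reads and filtered adapters and low-quality reads with SOAPnuke. The authors name Bismark for read processing, without a version, and the genome build is not given in the sources used here.

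For each cytosine the authors deposited a methylated value, read here as a score because it is a whole number that no longer behaves as a raw count. The authors also deposited a total per cytosine, read here as a coverage signal, and every deposited cytosine had a total of at least 10 in all 8 calves of an organ. The deposited percent equals 100 times the score over the coverage within 0.005. The authors' tables mark the nearest transcript start, the distance to it, and whether a cytosine lies in a promoter, exon, intron, CpG island or shore.

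Features seen in the values point to changes made after read counting, and no header or label records such a step. In 12 libraries the coverage value 18 never occurs, a gap that scaling and rounding would leave. They are 2 of liver, 4 of pituitary and 6 of adrenal gland. In every organ, 1 direction of variation between calves is nearly absent, with 0.508% of variance in pituitary to 0.885% in muscle, where the next smallest direction held 13.4% to 15.5%. In liver, hypothalamus, pituitary and testicle it mainly set calf MOET_3213 against MOET_5932 (weights 0.821 and -0.53 in liver), and in muscle and adrenal gland both against other calves. The values of MOET_3213 scattered at 0.35 to 0.73 and those of MOET_5932 at 0.65 to 0.89 of the binomial expectation, against 0.75 to 1.54 in the other calves. The 4 MOET calves are therefore not 4 independent values, their SD may be too small, and n counts calves. In the adrenal gland, mean levels per cytosine span 66.5% to 84.0%, with 77.3% to 80.3% between their 5th and 95th percentiles against 27.4% to 95.9% in liver, and 426 percentages exceed 100. Adrenal values were therefore left out of comparisons between organs, which had been planned with all 6 organs.

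Mean coverage per cytosine was 14.3 to 16.5 per library and the median 13 to 15. At a level of 75% such coverage gives a 95% interval for 1 cytosine in 1 calf of about 21.9 to 23.5 points on either side. These intervals cover counting error only. Differences of single cytosines in single calves are therefore not resolved at this depth, and groups of calves or of cytosines were compared.

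Transcripts were joined to gene symbols through a RefSeq table for ARS-UCD2.0, used only for names, by accession without its version. Of the transcripts, 70.6% to 71.5% had a symbol, and names were withheld where the symbol's chromosome differed. Genes with a locus symbol only were counted but not named, and microRNA genes were named only within 5000 bp of a cytosine. Promoters ran from 1500 bp upstream to 500 bp downstream of the start and needed 3 cytosines. No genome was used, so repeats were not analysed here, and island marks are those of the authors.

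Levels per calf (methylated score over coverage, summed) were compared between IVP and MOET calves by two-sided exact permutation tests over the 70 assignments, and between organs by two-sided exact sign-flip tests over the 8 calves. P values were corrected by Benjamini and Hochberg within each family. Cytosines with a pooled level of 5% to 95%, and promoters, were tested by a binomial quasi-likelihood model with overdispersion moderated by limma and a floor of 1. They were called at an adjusted p under 0.05 and a difference of at least 10 points for cytosines and 5 for promoters. Organ-specific promoters and cytosines were tested with limma on the within-calf difference from the mean of the other organs, each organ on its own cytosines, at 20 points or more. Promoters needed 3 cytosines in each of 5 organs, because only 50 promoters had 3 cytosines shared by these organs. Gene lists, 12 of pathways and 16 of cell-type markers, were compared by the mean over measured members. R 4.3.3, limma 3.58.1, data.table (version 1.17.8) and matplotlib 3.10.9 were used.

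Groups, comparisons, tests, gene lists, thresholds and most alternatives were set before the data were examined. The named genes followed a rule of that time. Per organ it takes the 8 called promoters with the largest difference in each direction, or the 6 with the smallest p, named as not called, where fewer than 4 were called. It also takes the 8 called cytosines with the largest difference in each direction, without overlap of the groups and in or within 5000 bp of a named gene. Called members of the lists are added, with the 6 most and 4 least methylated organ-specific promoters.

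The order in which the tests were chosen matters for the cytosine counts. Limma on a log scale with an offset of 0.02 and limma on percentages, each with and without the missing direction as covariate, were run first and their counts were seen. In liver, muscle, hypothalamus, pituitary, testicle and adrenal gland they called 8, 0, 12, 1, 32 and 0 on the log scale and 24, 0, 33, 0, 62 and 0 on percentages. With the covariate they called 0 in every organ on the log scale and 2, 0, 0, 0, 9 and 0 on percentages. Simulated changes were then added to liver, and limma on the log scale recovered 0 of 100 changes of 60 points, limma on percentages 90 and the quasi-likelihood model 100. The quasi-likelihood model, the test first planned, was then kept for the results before its own counts were seen. It recovered 20 of 100 changes of 30 points in cytosines, and in promoters 40 of 100 changes of 10 points and all 100 of 25 points. These promoter changes were made together among 727 promoters, so the correction was milder than it is with few changes. The simulated spread between calves was also set low, at 0.005. The promoter recovery therefore does not show that a single change of 25 points would have been called in the real data. The organ test, tested on simulated data, recovered 100 of 100 changes of 25 points with 7 false calls among 4000. Of the 1084 calls, 115 were also called by limma on percentages, and 11 by limma on percentages with the missing direction as covariate.

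Other choices were made after values were seen. These were the minimum of 3 other organs for organ-specific cytosines, the check on the same cytosines, the test of chromosome clustering, the handling of names the comparison within libraries alike in rescaled coverage, the splits without MOET_3213, the covariates parting other calves and the omission of the adrenal gland. Alternatives covered coverage, weighting, window, thresholds, models, suspected sequence variants and each calf left out.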

Results

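DNA methylation was measured in 6 organs of 8 male dairy calves, which gave 48 libraries. In each organ 4 calves came from embryos produced in vitro (IVP) and 4 came from multiple ovulation and embryo transfer (MOET), in which fertilisation takes place inside the donor cow. The 6 organs were liver, muscle, hypothalamus, pituitary, testicle and adrenal gland, and the calf number paired the organs of the same animal. The calves were 98 to 104 days old, except calf MOET_3213 at 144 days. In each organ the values of calf MOET_3213 were nearly fixed by those of MOET_5932 and the other calves, so the 4 MOET calves held fewer than 4 independent values. Once the mean of each cytosine was removed, MOET_3213 correlated with MOET_5932 at 0.812 to 0.888 in liver, hypothalamus, pituitary and testicle, and at -0.673 in muscle and -0.706 in adrenal gland. Pairs of calves without MOET_3213 had -0.334 to 0.123 within an organ. Pairs of MOET_3213 with calves other than MOET_5932 are not part of this range. The tables held 310430 cytosines in liver, 946649 in muscle, 443839 in hypothalamus, 369342 in pituitary, 453899 in testicle and 285771 in adrenal gland, each covered at least 10 times in all 8 calves. Total coverage per library was 4460253 to 5055478 in liver, 13527385 to 14250766 in muscle and 6431406 to 7064381 in hypothalamus. It was 5557497 to 6085281 in pituitary, 6545418 to 6888349 in testicle and 4412623 to 4710523 in adrenal gland.

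The first question was whether the way the embryo was made left a difference in the methylation of whole organs at about 3 months of age. No organ differed beyond the spread between calves. Muscle came closest, with 75.5% ± 0.157 (SD, n = 4) of covered cytosines methylated in IVP calves and 74.9% ± 0.577 in MOET calves (exact permutation test, two-sided, p = 0.0571, adjusted p = 0.24). Pituitary had the widest gap, 69.8% ± 1.76 against 68.4% ± 0.797 (n = 4 each, exact permutation p = 0.2). Liver held 75.2% ± 0.442 against 75.5% ± 0.437, hypothalamus 79.6% ± 0.643 against 79.0% ± 0.579 and adrenal gland 79.2% ± 0.669 against 78.5% ± 0.804 (n = 4 each, exact permutation p = 0.171 in each). Testicle held 77.6% ± 0.472 in IVP and 77.6% ± 0.18 in MOET calves (n = 4 each, exact permutation p = 1). The smallest p that 4 against 4 calves allow is 0.0286, with which an organ alone could not have passed the correction over 6. The adjusted p over the 6 organs was 0.24 in all except testicle, at 1. Without MOET_3213 the exact permutation p was 0.0857 in muscle and 0.143 to 0.971 in the other organs (n = 4 against 3). The embryo-origin difference itself was compared between organs in 15 pairs, of which liver against adrenal gland had the smallest exact permutation p, 0.0286 (adjusted p = 0.429, n = 8 calves). In pituitary, 1 IVP and 3 MOET libraries had rescaled coverage, in liver 1 of each origin had, and in adrenal gland all except 1 of each origin had. In liver the 3 IVP and 3 MOET libraries without rescaled coverage held 75% ± 0.465 against 75.4% ± 0.485 (exact permutation p = 0.2, n = 3 each). In adrenal gland the 3 and 3 with rescaled coverage held 79.0% ± 0.554 against 78.8% ± 0.528 (exact permutation p = 0.6, n = 3 each). The smallest p that 3 against 3 allow is 0.1, and in pituitary 1 origin had 1 library in each subset, too few for a value.

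**Figure D1:**
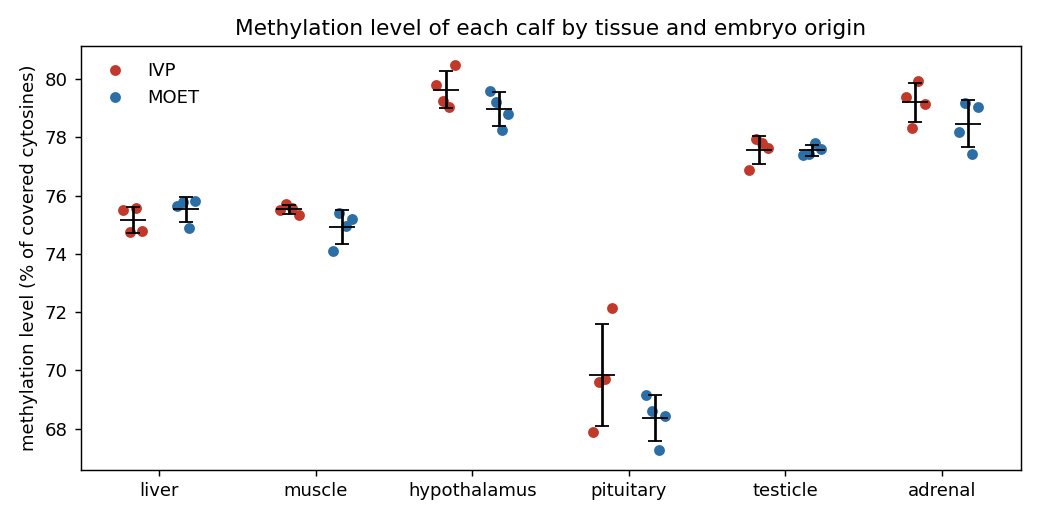
Methylation level (% of covered cytosines, vertical axis, not starting at 0) by organ, with 1 point per calf for IVP (red) and MOET (blue) and black bars for mean and SD over 4 calves. The muscle means were 75.5% in IVP and 74.9% in MOET calves, and no organ passed the exact test.

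The same question was asked of promoters, exons, introns, intergenic sequence, CpG islands, island shores and chromosome X. Intergenic cytosines of muscle were 74.5% ± 0.158 methylated in IVP and 73.9% ± 0.6 in MOET calves, the smallest p of the 42 combinations (exact permutation p = 0.0571, adjusted p = 0.457, n = 4 each). The pituitary gap was widest outside genes, with intergenic levels of 67.5% ± 2.16 against 65.8% ± 0.918 (exact permutation p = 0.229, adjusted p = 0.457, n = 4 each). No region of any organ passed the correction over 42 tests. A region alone could not have passed it, because the smallest possible exact permutation p of 0.0286 is too large for that. Promoters and CpG islands were less methylated than introns in 5 of the organs. Promoters held 52.8% ± 0.349 in liver, 51.0% ± 0.442 in muscle, 55.3% ± 0.628 in hypothalamus, 47.2% ± 1.15 in pituitary and 51.3% ± 0.358 in testicle (SD, n = 8). Introns held 78.1% ± 0.375, 77.1% ± 0.503, 81.3% ± 0.506, 72.9% ± 1.17 and 79.2% ± 0.296 in the same organs. CpG islands of liver, at 52.6% ± 0.953, lay above those of the other 4 organs, at 45.1% to 46.9%, each measured on its own cytosines. In the adrenal gland the classes could not be told from each other, at 78.8% to 79.0%.

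Single cytosines were called between IVP and MOET calves in 5 of the 6 organs, but mixed splits of the calves called as many in each of these, so the counts did not set embryo origin apart. Of 80 cytosines named by rule, 5 were also called by limma with the missing direction as covariate, among them MTREX in liver and COMMD7, CFAP54 and MAP1B in testicle. In liver, an intronic cytosine 18169 bp downstream of the start of MTREX, an RNA helicase of the nuclear exosome, was unmethylated in IVP calves and 69.5% ± 8.86 methylated in MOET calves (n = 4 each, chromosome 20 position 23811931, adjusted p = 3e-04). An intronic cytosine assigned to KBTBD8, an adaptor of a ubiquitin ligase, went the other way, at 96.7% ± 3.92 in IVP and 24.7% ± 17.4 in MOET calves (chromosome 22 position 34456871, adjusted p = 3e-04). Upstream of ACE, the angiotensin-converting enzyme, a cytosine held 29.5% ± 20.6 in IVP and 97.5% ± 5 in MOET liver (chromosome 19 position 47795869, adjusted p = 0.00126). An exonic cytosine of DNMT3B, a methyltransferase that sets new methylation marks, held 11.3% ± 18.4 against 70.1% ± 17.2 in liver (chromosome 13 position 62158904, adjusted p = 0.0139). Genes were assigned by the nearest annotated start, so the exon or intron mark may belong to an overlapping gene.

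In muscle, introns nearest to PMS1, a mismatch repair protein, and NCOR1, a corepressor of nuclear receptors, held more methylation in IVP calves. The PMS1 cytosine stood at 91.1% ± 7.43 against 38.9% ± 22.8 (chromosome 2 position 6535052) and the NCOR1 cytosine at 65.4% ± 21.1 against 14.1% ± 15.2 (chromosome 19 position 33382649, adjusted p = 0.0178, n = 4 each). ERCC8, a nucleotide excision repair factor, was lower in IVP muscle, at 9.09% ± 18.2 against 74.4% ± 21.6 (chromosome 20 position 18373788, adjusted p = 0.00659). Among the sites named by rule, those of ARL15, TRIO, COMMD1 and TEFM were also lower, those of FRMD6, SYT14 and EDEM1 were higher, and MAST4 had 1 of each. Some of these genes had further called sites in muscle. In hypothalamus, an intronic cytosine of IGF2BP2, which binds the messenger RNA of a growth factor, held 96.1% ± 4.49 in IVP and 33.8% ± 15.3 in MOET calves (chromosome 1 position 81501244, adjusted p = 0.00206). The same cytosine held 91.2% ± 10.4 against 43.6% ± 23.4 in pituitary (adjusted p = 0.0362). ALDH5A1, which breaks down a product of the transmitter GABA, had 3 lower intronic cytosines in IVP hypothalamus, of which the 1 at chromosome 23 position 33202586 held 12.4% ± 21.8 against 75.2% ± 16.9. A cytosine assigned to SCGN, a calcium-binding protein of neuroendocrine cells, and sites of PRICKLE2 and TRAF5 were also lower there, while NUP35, CLTC and RPA1 had higher sites.

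In pituitary, PDE4D, a phosphodiesterase that degrades cyclic AMP, had an intronic cytosine at 19.5% ± 22.6 in IVP and 88.9% ± 10.3 in MOET calves (chromosome 20 position 19939299, adjusted p = 0.0133, n = 4 each). MMD2 went the other way, at 91.1% ± 3.58 against 28.6% ± 11.3 (chromosome 25 position 39096896, adjusted p = 0.00565). MAP1B, a microtubule protein of neurons, was lower in IVP pituitary, at 42% ± 22.3 against 92.5% ± 9.57, and in IVP testicle, at 38.0% ± 5.48 against 98.4% ± 3.13 (chromosome 20 position 9481842, adjusted p = 0.0453 and 8.16e-04). In testicle, IVP calves were higher at sites of XPO5, NTN1, a guidance cue for axons, and SLC40A1, which exports iron from cells. They were lower at ASIC2, an ion channel opened by acid, with 35.4% ± 27.3 against 100% ± 0 (chromosome 19 position 16121019, adjusted p = 0.00147). Coverage at the named cytosines was 10 to 31 per calf.

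Many of these differences recurred across organs of the same animals. COMMD7 was higher in IVP liver, at 86.5% ± 5.64 against 26.6% ± 13.3, in testicle, at 96.8% ± 3.73 against 32.5% ± 8.67, and in hypothalamus, at 79.6% ± 14.2 against 28.7% ± 8.39 (chromosome 13 position 62108145, n = 4 each). DHRS7B was higher in IVP muscle, hypothalamus and testicle, with 80.5% ± 15.2 against 10.1% ± 15.8 in hypothalamus (chromosome 19 position 35167762). TCTE1, a protein of the sperm flagellum, and CUL9 were lower in IVP liver and pituitary, CFAP54 higher in liver and testicle, and PRICKLE2 lower in hypothalamus and testicle. RCAN2, a regulator of calcineurin, was lower in IVP muscle, hypothalamus, pituitary and testicle at 3 cytosines on chromosome 23, with 19.2% ± 28.3 against 84.7% ± 6.51 at position 19611988 in testicle. In all, 116 of 945 positions were called in more than 1 organ. Of these, 21 were called in at least 3 organs and 2 in 4, at chromosome 19 position 61620757 and chromosome 2 position 7024849, neither assigned to a gene with a name and both chosen after their values were seen. Cytosines at which the 8 calves spanned at least 40 points in each other organ that held them were marked as suspected sequence variants. Of the 601 calls at cytosines measured in another organ, 561 (93.3%) had this mark. Calls were chosen for large differences between calves, and 71.9% of uncalled cytosines with an equally wide span in the same organ had it. The mark was on the cytosines given above for COMMD7, DHRS7B, TCTE1, CUL9, CFAP54, PRICKLE2, IGF2BP2, PDE4D, MAP1B, TRAF5, XPO5 and NTN1, on TRIO in muscle, and on 2 of the 3 of RCAN2 and of ALDH5A1. In muscle it was on 1 of 2 called cytosines of EDEM1, 2 of 3 of COMMD1 and 1 of 5 of MAST4, and in hypothalamus on 1 of 3 of RPA1. RYR1 and PPP1R9A, below, had it too. The cytosines with printed values of MTREX, KBTBD8, ACE, DNMT3B, PMS1, NCOR1, ERCC8, MMD2 and ASIC2 were not measured in another organ.

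Over the 6 organs, 1084 of 2559577 tests were called, 537 higher and 547 lower in IVP calves, with a median absolute difference of 49.4 points. By organ the counts, higher and lower in IVP, were 79 and 86 in liver, 163 and 154 in muscle, 113 and 122 in hypothalamus, 41 and 44 in pituitary and 141 and 141 in testicle. The adrenal gland had 0 calls by the binomial quasi-likelihood test, 0 by limma on percentages and 404 by a binomial test that ignores the spread between calves. By the quasi-likelihood test 4908 adrenal cytosines, 1.72%, had an unadjusted p under 0.05, where 14289 would be expected without any difference. The other organs had 5.3% to 7.5%. The test was therefore conservative in adrenal gland, and 0 calls do not show that this organ had no differences. Introns held 513 calls, exons 32, promoters 22 and island shores 56, and 312 calls lay in or near a gene with a symbol. Among the fixed gene lists, 3 genes had a called cytosine. DNMT3B belonged to the DNA methylation machinery. RYR1, the calcium release channel of skeletal muscle, was unmethylated in IVP and 50% ± 37.9 methylated in MOET liver at chromosome 18 position 48256489 (adjusted p = 0.0296), and 56.7% ± 41.6 in MOET pituitary (adjusted p = 0.0352). PPP1R9A, an imprinted gene in other mammals, held 27.8% ± 33 in IVP and 0% ± 0 in MOET muscle (n = 4 each, chromosome 4 position 12342378, adjusted p = 0.0305). Other splits of the same 8 calves into 4 and 4 gave at least as many calls in 3 of 35 splits in liver, 10 in muscle, 6 in hypothalamus, 3 in pituitary and 5 in testicle, the real split included. Without MOET_3213 the counts were 502, 1375, 688, 382 and 666, and 12, 9, 14, 15 and 19 of the 35 splits of the other 7 calves called as many. The counts also depended on the model, and limma on percentages called 24, 0, 33, 0 and 62 cytosines in these organs.

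**Figure D2:**
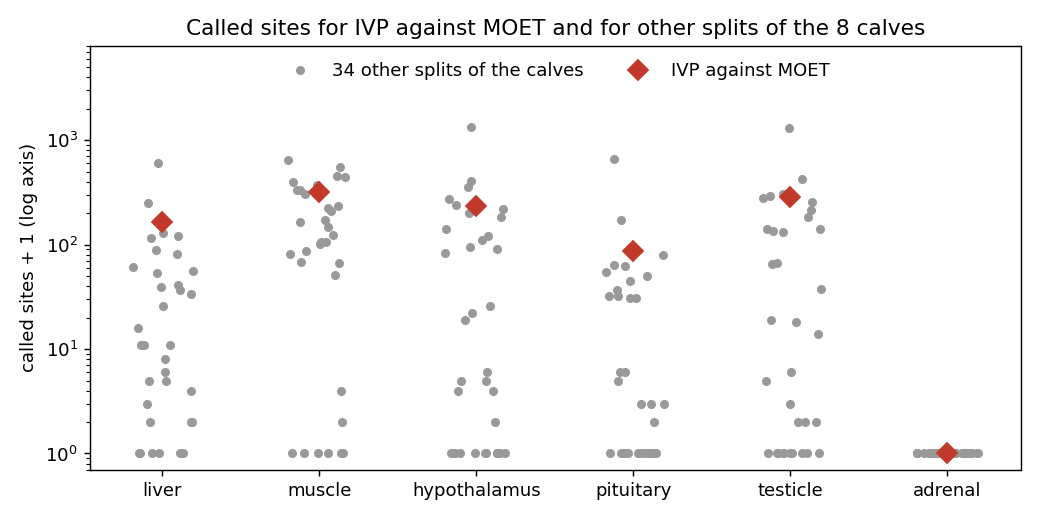
Called cytosines plus 1 (logarithmic vertical axis) by organ for IVP against MOET (red diamonds) and for the 34 other splits of the 8 calves into 4 and 4 (grey points). In each organ except adrenal gland at least 1 other split called more, up to 1347 in hypothalamus against 235 for the real split.

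The called cytosines were concentrated on a few chromosomes. Chromosome 19 held 16.4% of calls and 3.07% of tested cytosines. Chromosomes 20, 23, 22, 16 and 2 held 9.23%, 9.13%, 8.76%, 8.58% and 8.30% of calls, against 2.66%, 2.40%, 2.62%, 3.5% and 4.58% of tested cytosines. These 6 chromosomes held 655 of the 1084 calls. Within an organ, 44.7% of calls in pituitary to 74.5% in muscle lay within 1000000 bp of another call more than 1000 bp away. The highest of 100 random draws of tested cytosines reached 23.5% and 30.6% in these organs.

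**Figure D3:**
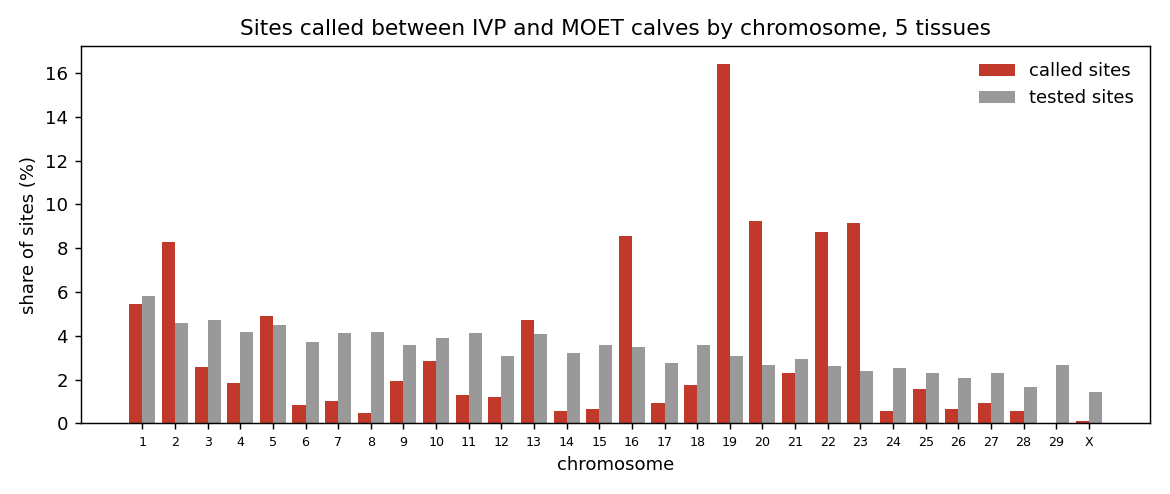
Share of called cytosines (red bars) and of tested cytosines (grey bars) in percent (vertical axis) on each chromosome (horizontal axis), summed over the 5 organs with calls. Chromosome 19 held 16.4% of calls against 3.07% of tested cytosines.

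No promoter differed between IVP and MOET calves after correction in any organ. The promoter of PLAGL1, an imprinted zinc finger gene that restrains cell growth, came closest, at 98.1% ± 1.26 in IVP and 86.0% ± 2.95 in MOET testicle (n = 4 each, chromosome 9 positions 81460519 to 81460535, adjusted p = 0.109). Its liver promoter, chosen after its values were seen, held 86.0% ± 3.08 against 74.9% ± 7.24 (adjusted p = 0.416). CALCA, which encodes calcitonin and a related peptide, held 63.7% ± 7.65 in IVP and 82.9% ± 8.79 in MOET liver (chromosome 15 positions 37628607 to 37628795, adjusted p = 0.23). In muscle it held 44.8% ± 4.35 against 61.2% ± 4.55 (adjusted p = 0.692). In hypothalamus, IL1R1, the interleukin 1 receptor, held 65.8% ± 8.6 against 86.9% ± 2.44 and MIEN1 44.8% ± 3.12 against 27.4% ± 6.81 (adjusted p = 0.426 each). The 3 cytosines of IL1R1, at chromosome 11 positions 6857944 to 6876014, lay further apart than 1 promoter window, as did those of GTPBP3 below. In pituitary, SYT6 held 82.7% ± 9.34 against 61.0% ± 7.75 (adjusted p = 0.45) and CALB1, a calcium-binding protein, 62.2% ± 5.27 against 45.8% ± 5.52 (adjusted p = 0.485). In muscle, LRRC61 held 16.9% ± 4.21 against 5.07% ± 2.7 (adjusted p = 0.628), and in liver DCXR held 81.3% ± 3.76 against 94.3% ± 2.65 (adjusted p = 0.23). In adrenal gland the 6 promoters with the smallest p, among them ATP11A and GTPBP3, each had an adjusted p of 0.9. The binomial quasi-likelihood test called 0 of 6310 promoters, and 54, 115, 63, 74, 75 and 24 had an unadjusted p under 0.05 in liver, muscle, hypothalamus, pituitary, testicle and adrenal gland. Limma with the missing direction as a covariate also called 0, with 49, 126, 46, 66, 66 and 44 at an unadjusted p under 0.05, while limma on the log scale called 2 in testicle.

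Imprinted genes, hormone axes and metabolic pathways were then compared as groups through the mean promoter level of their measured members. Among imprinted genes in muscle, DLK1, a growth regulator, held 66.6% ± 5.89 in IVP and 76.2% ± 4.46 in MOET calves (n = 4 each). Adjusted over the list alone it passed, and over all promoters it did not (adjusted p = 0.692). In testicle, PLAGL1 and NNAT, at 55.7% ± 12.4 against 76.3% ± 8.18, were the 2 of 5 imprinted promoters that passed when adjusted over the list alone. Over all promoters 0 of the 5 passed (adjusted p = 0.109 and 0.466). The imprinted group as a whole held 83.9% ± 1.83 against 86.6% ± 1.78 in muscle, where 2 of 3 members were lower in IVP (exact permutation p = 0.0857, adjusted p = 0.615, n = 4 each). In testicle the group held 80.9% ± 1.85 against 82.4% ± 3.22 (exact permutation p = 0.457, n = 4 each). The 2 measured stress axis promoters of muscle averaged 69.2% ± 2.05 in IVP and 78.4% ± 6.54 in MOET calves (exact permutation p = 0.0571, adjusted p = 0.615, n = 4 each). Lipid metabolism held 58.1% ± 0.598 against 59.8% ± 1.92 in testicle (exact permutation p = 0.143, n = 4 each). The 28 combinations of list and organ with at least 2 measured promoters included insulin signalling, the growth hormone axis, the gonadal axis, steroidogenesis, appetite control, muscle development and the DNA methylation machinery. None passed over the 28, and an exact permutation p of 0.143 or more was found for all except the muscle stress axis and imprinted lists. A combination alone at the smallest possible exact permutation p, 0.0286, could not have passed, here or over gene bodies. Over gene bodies, 4 of 155 combinations had an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.738 (n = 4 each). The gonadal axis held 78.4% ± 0.995 in IVP and 75.6% ± 0.801 in MOET liver, higher in 9 of 9 members, and appetite control 74.5% ± 0.758 against 72.0% ± 1.99 in liver. Lipid metabolism held 81.0% ± 1.33 against 82.8% ± 0.682 in testicle, lower in 16 of 19 members, and the hepatocyte list 76.0% ± 0.882 against 73.5% ± 1.11 in hypothalamus.

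The direction of embryo-origin differences was compared across organs over shared cytosines, which are not independent replicates. Liver against testicle had a correlation of 0.175 over 89290 cytosines and liver against hypothalamus 0.174 over 81984. Muscle followed testicle at 0.144 and hypothalamus at 0.143. The median over 15 pairs was 0.139. Of the 35 splits of the calves, 7 gave a median as high, with 0.158 as the highest and 0.107 as the middle of the others. Liver against testicle had a middle value of 0.172 in the other splits. Without suspected sequence variants the median was 0.0859, and 2 of 35 splits gave as much, with 0.0932 as the highest and 0.064 as the middle of the others.

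Organs of the same calves differed from each other. At 20553 cytosines shared by 5 organs, pituitary was the least methylated, at 57.0% ± 2 (SD, n = 8), and testicle the most, at 68.3% ± 0.759. Liver held 67.2% ± 0.604, hypothalamus 65.9% ± 0.914 and muscle 63.4% ± 0.552. Pituitary lay below testicle by 11.2 points on average and below liver by 10.2, and each of these held in 8 of 8 calves (exact sign-flip permutation p = 0.00781, adjusted p = 0.00868). All 10 pairs passed, of which liver over hypothalamus, 1.34 points in 7 of 8 calves, had the largest exact permutation p, 0.0156. Without MOET_3213 all 10 pairs passed as well, with a largest exact permutation p of 0.0312 (n = 7). The adrenal gland was left out because its cytosines had nearly equal levels.

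**Figure D4:**
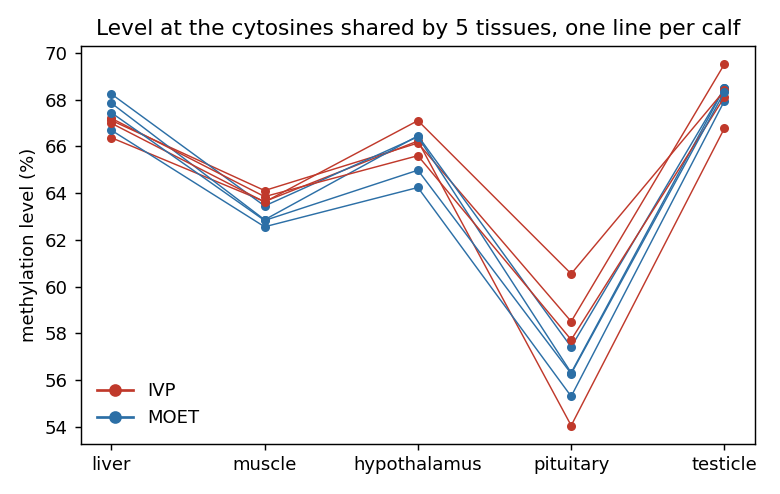
Methylation level (%, vertical axis, not starting at 0) at 20553 cytosines shared by 5 organs, with 1 line per calf, IVP in red and MOET in blue. Pituitary was lowest in each of the 8 calves, at 54.1% to 60.6%.

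Promoters that set an organ apart were sought among the 135 promoters measured in 5 organs, in the same calves. In liver, GLYAT, an enzyme that joins glycine to acyl groups in liver mitochondria, held 33.7% ± 7.18 against 75.6% in the other organs (n = 8, chromosome 15 positions 82141771 to 82143338, adjusted p = 2.53e-07 by limma). GIPR, the receptor of the gut hormone GIP, held 68.8% ± 2.86 in liver and 64.4% ± 4.93 in hypothalamus but 22.6% ± 4.58 in testicle. In muscle, HACD2, which takes part in the elongation of fatty acids, held 44.9% ± 5.69 against 84.3% (chromosome 1 positions 67952952 to 67953379), and CACNG5, a calcium channel subunit, 57.4% ± 7.6 against 79.7%. BTG2, which restrains cell division, held 91.8% ± 4.55 in hypothalamus against 39.0%, and 24.2% ± 3.79 in pituitary against 55.9%. PRPF31, a splicing factor, held 30.7% ± 4.61 in hypothalamus against 88.5% ± 4.06 in liver. In pituitary, the promoter of the microRNA MIR379 held 32.4% ± 9.36 against 79.2% (chromosome 21 positions 65911297 to 65911470). In testicle, the olfactory receptor OR7A122 held 72.7% ± 7.22 against 43.7%, OR7A126 66.8% ± 2.85 against 44.2%, and NOCT, a clock-controlled enzyme, 42% ± 4.67 against 64.0%. Each of these held in 8 of 8 calves. On cytosines shared by the organs, NOCT was lower by 18.5 points and not called. Called promoters, higher and lower, were 4 and 7 in liver, 2 and 7 in muscle, 11 and 3 in hypothalamus, 2 and 7 in pituitary and 9 and 2 in testicle. Organs were measured on their own cytosines, and at 22 of the 135 promoters, with 8 of the 54 calls, these lay further apart than 1 promoter window. Of 35 named pairs of promoter and organ, 11 could be recomputed on the same cytosines, of which 10 kept their direction and 6 their call. Those of GIPR, HACD2, BTG2, PRPF31 and MIR379 could not be recomputed, so their differences may also follow which cytosines were measured. CALB1, at 26.0% ± 2.73 in liver against 61.1%, lost its call there and differed by 4.11 points in the other direction.

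Single cytosines gave a wider view of how genes of the lists differed between organs. In liver, 2 intronic cytosines of IGFBP4, which binds insulin-like growth factors, held 3.15% ± 2.29 against 63.4% in the other organs (n = 8, adjusted p = 1.77e-07 by limma). LEPR, the leptin receptor, held 33.6% ± 10.4 against 84.2% at the 1 cytosine tested. GYS2, the liver glycogen synthase, held 40.1% ± 6.92 against 90.4% at 1 of 3 tested. CPT2, which brings fatty acids into mitochondria, held 42.5% ± 11.5 against 90.8%, also at 1 of 3. In muscle, 2 genes of the myofibre list had a lower cytosine, namely CASQ1, which stores calcium, with 1 of 3 tested, at 38.7% ± 10.5 against 87.1%, and RYR1, with 1 of 7, at 40.6% ± 12.9 against 81.8%. PAX3 and MYOG, both regulators of muscle formation, were higher in muscle at 57.3% ± 13.1 against 6.73% and 69.3% ± 9.11 against 43.7%. OXT, the oxytocin gene, held 20.7% ± 9.74 in pituitary against 59.7% at 1 of 2 cytosines, and the same cytosine held 71.8% ± 11 in hypothalamus against 42.7%. Both OXT cytosines were higher in liver, at 79.5% ± 6.43 against 47.9%, and lower in muscle, at 35.4% ± 11.2 against 62.5%. List genes that mark other organs also had lower cytosines. In liver, SLC1A2 of the astrocyte list held 40.4% ± 17.7 against 80.3%. In pituitary, MYL2 of the muscle development list held 48.9% ± 12.7 against 85.9%. There WT1 of the Sertoli cell list held 46.5% ± 6.27 against 68.1% at 1 of 2 cytosines.

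Several steroid genes had lower cytosines in testicle. NR5A1, the regulator of steroid-making cells, held 51.0% ± 14.2 in testicle against 85.0% in the other organs at 1 of 2 cytosines (n = 8, adjusted p = 1.5e-04 by limma). FDXR, which passes electrons to steroid enzymes, held 24.3% ± 11.4 against 62.8%, and CYP19A1, the aromatase, 33.8% ± 12.9 against 64.0%. These were the 3 called of the 12 steroidogenesis cytosines measured there, and all were lower. In hypothalamus the same CYP19A1 cytosine held 93.1% ± 4.87 against 49.2%, and 2 cytosines of AKR1C3 were higher too. PGR, the progesterone receptor, held 17.9% ± 10.3 in testicle against 58.4% at 1 of 2 cytosines. KIT, a receptor of germ cells, held 63.0% ± 10.5 against 88.0% there. PTPN1, a phosphatase that acts on the insulin receptor, held 28.0% ± 18 in testicle against 77.3% at 2 of 5 cytosines. For FSHR, the receptor of follicle-stimulating hormone, 1 of 4 cytosines was higher in testicle, at 81.1% ± 13.2 against 59.5%. The same cytosine was lower in muscle, at 42.6% ± 8.13 against 72.3%. Among imprinted genes, PLAGL1 held 21.7% ± 7.01 in pituitary against 66.6% at 1 of 2 cytosines. The same cytosine, 1 of 3 tested in hypothalamus, held 79.3% ± 12.5 there against 52.2%. In the DNA methylation machinery, 1 of 2 cytosines of UHRF1, which guides maintenance of the mark, held 40.0% ± 12.6 in liver against 76.5%. The same cytosine held 94.4% ± 6.63 in hypothalamus against 58.3%. Of the hepatocyte list, 0 of 6 liver cytosines were called by limma, and of the neuron list 1 of 5 in hypothalamus, RBFOX3, was higher.

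Pituitary stood below the other organs widely. It was lower at 5087 and higher at 319 of 51133 cytosines, and the lower ones made up 10.7% of intergenic but 1.5% of island cytosines. Muscle was also mostly lower, at 2258 cytosines against 498 higher of 51205. Hypothalamus was mostly higher, at 1911 against 557 of 50445, as was testicle, at 2334 against 1145 of 52958. Liver had 1494 higher and 1132 lower of 49568. Cytosines had to be present in at least 3 of the other 4 organs, a minimum chosen after values were seen, and with 2 or with 4 the same organs stayed mostly lower or mostly higher.

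**Figure D5:**
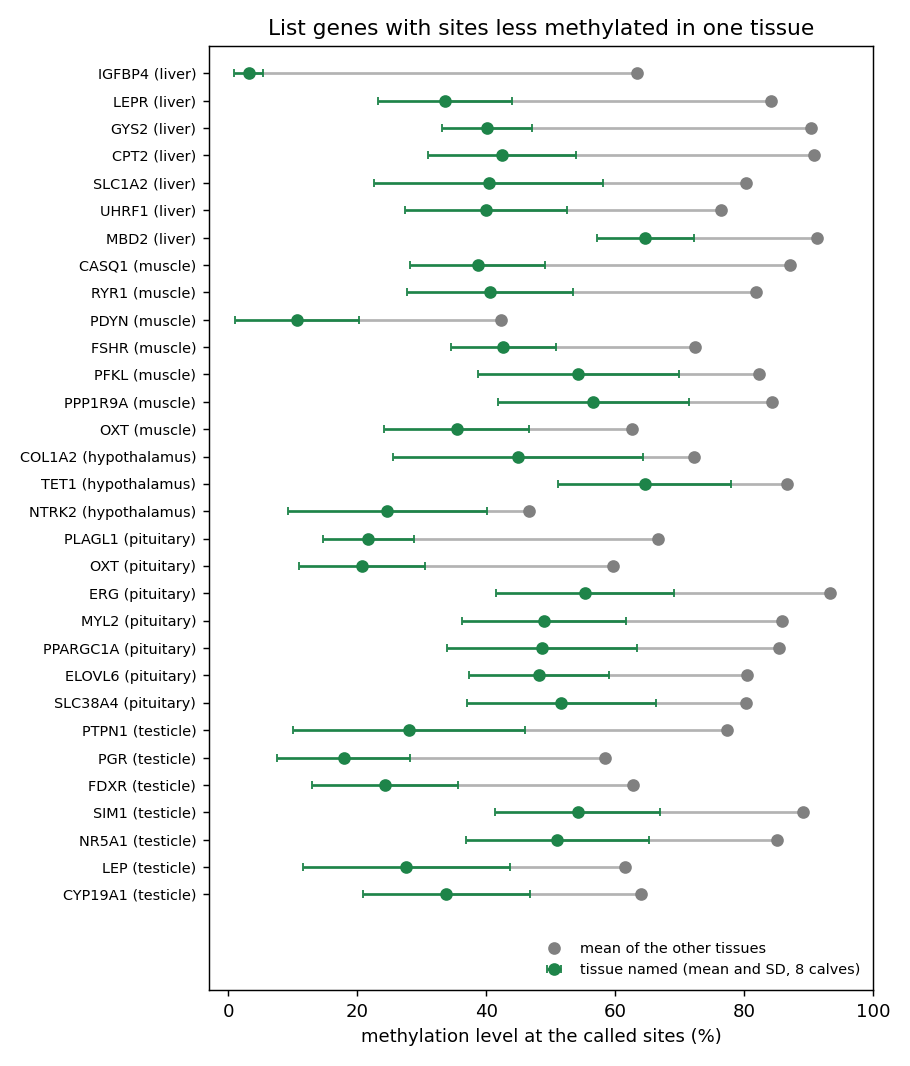
Methylation level (%, horizontal axis) at called cytosines of genes from the fixed lists that were lower in the named organ (green point and bar, mean and SD over 8 calves) than in the other organs of the same calves (grey point). A selection of up to 7 genes per organ is drawn, led in liver by IGFBP4 at 3.15% against 63.4%.

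Gene bodies of the measured list members differed between organs as well. Of 16 lists, 14 were higher in hypothalamus and 14 lower in pituitary, and each of these passed the correction. In testicle 14 had a higher mean, of which 9 passed, and in muscle 14 a lower mean, of which 13 passed. The same directions held over all 4805 measured gene bodies, at 3.60 points higher in hypothalamus, 1.64 higher in testicle, 4.82 lower in pituitary and 1.64 lower in muscle. Each organ was measured here on its own cytosines, and hypothalamus was highest. At the 20553 cytosines shared by 5 organs, hypothalamus, at 65.9%, lay below liver, at 67.2%, and testicle, at 68.3%. The list differences may therefore also follow which cytosines were measured. The exact test asks whether a list differed between organs, not whether it differed more than other genes. The 5 measured of 28 steroidogenesis genes averaged 66.8% ± 2.8 in pituitary against 83.6% in the other organs and 88.8% ± 2.18 in hypothalamus against 78.1%. They averaged 85.0% ± 2.53 in testicle against 79.0%, higher in 8 of 8 calves (n = 8, exact sign-flip permutation p = 0.00781 each). The 7 measured of 45 imprinted genes averaged 73.4% ± 2.39 in liver against 79.5% and 85.4% ± 0.745 in hypothalamus against 76.5% (exact permutation p = 0.00781 each). Insulin signalling genes, 12 measured of 37, averaged 69.5% ± 1.89 in muscle against 75.5%, with 9 members lower, and 79.7% ± 1.98 in liver against 72.9% (exact permutation p = 0.00781 each, n = 8). The 7 measured of 30 germline genes were lower in testicle on average, at 67.9% ± 1.25 against 71.4%, although 2 of 7 members were lower, and higher in hypothalamus, at 79.3% ± 1.92 against 68.5% (exact permutation p = 0.00781 each, n = 8). The 4 measured of 16 hepatocyte genes were higher in liver, at 76.4% ± 2.01 against 72.3%, in 8 of 8 calves, although 2 of 4 members were lower (exact permutation p = 0.00781).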

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

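All the results in this part were picked by their spread after the values were seen, and no test was planned for them. SF3B5, a splicing factor gene, had 1 IVP adrenal library far from the other 3. Its promoter held 40.9% in calf IVP_5833 and 77.4% to 79.4% in the other 3 (gap over range 0.948). MIEN1 in hypothalamus held 17.2% in calf MOET_3217 and 30.2% to 31.7% in the other MOET calves (0.898), which widens its gap to IVP calves in the report. The muscle promoter of the microRNA MIR3604-2 held 59.3% in calf MOET_3213 and 33.3% to 37.7% in the other MOET calves (0.833). In liver, calf MOET_3218 was lower than the other MOET calves over all cytosines, at 74.9% against 75.7% to 75.8% (0.837), and in exons, at 70.1% against 71.2% to 71.4% (0.835). In testicle, island shores held 64.4% in calf MOET_3213 and 64.9% to 65.0% in the other MOET calves (0.862). Of 168 groups of 4 calves, 6 stood out in this way, where chance gives about 8.4. No explanation was tested for these values.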

How the results depend on the processing

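Several tests were chosen only after results were seen. Among models these were limma on percentages, with or without the missing direction, limma on the log scale with an offset of 0.02 and the binomial test without spread. Among samples these were libraries alike in rescaled coverage, organ levels without MOET_3213, and leaving out calves MOET_3213 and MOET_5932 together. The adrenal gland among the other organs was the first plan, given here as an alternative after its omission. Counts are given for liver, muscle, hypothalamus, pituitary and testicle in this order, and the cause was not tested except where stated.

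Called cytosines, 165, 317, 235, 85 and 282, were the most dependent result. A coverage minimum of 20 left 1, 0, 1, 1 and 0, windows of 1000 bp 2, 0, 0, 0 and 1, and limma on log2 ratios with a pseudocount of 1 called 62, 0, 102, 8 and 118. Limma with the offset called 8, 0, 12, 1 and 32, on percentages 24, 0, 33, 0 and 62, and with the missing direction 2, 0, 0, 0 and 9. Without suspected sequence variants 97, 373, 191, 38 and 192 were called. Ignoring the spread between calves gave 1645, 2564, 3529, 1605 and 2594, and 404 in adrenal gland. A minimum difference of 25 points and an upper coverage limit kept each count within 1.5 times. In liver the 6 libraries without rescaled coverage gave 595. In adrenal gland the 6 with it gave 0 cytosines, with 1705 of 285771 at an unadjusted p under 0.05.

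Leaving out 1 calf gave 80 to 502 cytosines in liver, 55 to 1479 in muscle, 140 to 688 in hypothalamus, 14 to 382 in pituitary, 151 to 666 in testicle and 0 in adrenal gland. In liver the count was 502 without MOET_3213, 317 without MOET_5932, 99 without IVP_5833 and 80 without IVP_5841. In muscle it was 1407 without IVP_3208, 1479 without IVP_3209, 1375 without MOET_3213, 1045 without MOET_5932, 182 without MOET_3217, 97 without MOET_3218, 76 without IVP_5833 and 55 without IVP_5841. In hypothalamus it was 688 without MOET_3213, 475 without MOET_5932, 432 without MOET_3217, 397 without MOET_3218 and 140 without IVP_5833. In pituitary it was 382 without MOET_3213, 50 without IVP_3208, 45 without IVP_5833, 32 without IVP_3209, 23 without MOET_3217 and 14 without IVP_5841. In testicle it was 666 without MOET_3213, 659 without MOET_5932, 437 without MOET_3217, 185 without IVP_5841 and 151 without IVP_5833.

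Called promoters stayed at 0 with each calf left out, with 5 cytosines per promoter and with a window of 500 bp. In testicle limma on log2 ratios called 1 and limma with the offset 2. The edgeR alternative was not run, because the values are not raw counts.

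The difference in global level, IVP minus MOET, ranged over left-out calves from -0.591 to -0.241 points in liver, 0.339 to 0.777 in muscle, 0.39 to 0.879 in hypothalamus, 0.709 to 2.13 in pituitary, -0.118 to 0.234 in testicle and 0.398 to 1.03 in adrenal gland. Testicle, at 0.00541, reversed to -0.118 without IVP_3209, -0.072 without IVP_5833, -0.023 without IVP_5841, -0.044 without MOET_3213 and -0.037 without MOET_3217. Muscle without MOET_3217, at 0.777, and pituitary without IVP_3208, at 2.13, reached the smallest exact permutation p that 4 against 3 calves allow, 0.0286, unadjusted. Coverage, weighting, an upper coverage limit and autosomes alone kept the direction and the side of the threshold. The correlation of origin effects across organs dropped to 0.0859 without suspected variants.

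Organ-specific promoters, 11, 9, 14, 9 and 11, fell to 2, 0, 3, 2 and 3 with 5 cytosines per promoter, where 53 and not 135 promoters were tested, and to 7, 2, 3, 4 and 0 at 30 points, a stricter demand by construction. With the adrenal gland among the other organs muscle had 5, hypothalamus 6 and pituitary 14, while adrenal promoters went from 43 to 22 with 5 cytosines. Without the calf as a block the counts were the same, and without MOET_3213 and MOET_5932 they were 12, 9, 14, 10 and 10. Organ-specific cytosines without these calves numbered 2708, 2658, 2454, 5514 and 3623. With a coverage minimum of 20, 6106, 5136, 4171, 7644 and 6626 cytosines were left to test between IVP and MOET calves, of 280178, 859476, 385241, 349576 and 399335.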

Other observations

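Tests of rescaled coverage, of the dependence of MOET_3213, of the missing direction, of the covariate, of haplotypes, of exchanged calves, of other splits for called cytosines, with or without MOET_3213, and of adrenal promoters were chosen only after the result was seen. Genes with several organ-specific cytosines, picked by hand for their function after their values were seen, are given here. The most such cytosines lay at other genes, with 37 of 264 tested lower in pituitary at MGC134232, 28 of 244 lower in muscle and 26 of 189 higher in hypothalamus at ORM1, 28 of 74 higher in testicle at WC1.3 and 26 of 137 lower in pituitary at GAT. These counts also follow the number of cytosines tested, and in pituitary 9.95% of all tested cytosines were lower. GLYAT, the glycine conjugation enzyme, had 13 lower cytosines in liver, at 35.9% ± 3.38 (SD, n = 8) against 72.4% in the other organs. It also had 21 lower ones in pituitary, at 36.8% ± 3.64 against 65.0%, and in muscle 8 lower, at 17.7% ± 2.10 against 48.6%, with 3 higher. In hypothalamus 13 were higher, at 68.2% against 37.6%, and in testicle 14, at 67.8% against 39.6%, with 3 lower. APOC4, an apolipoprotein, had 4 lower cytosines in liver, at 40.5% ± 9.41 against 71.2%, and MYBPHL 3, at 43.3% ± 7.38 against 92.6%. FEZF2, a transcription factor of the forebrain, had 3 lower cytosines in hypothalamus, at 51.5% ± 9.28 against 85.8%. RFX4, a neural transcription factor, had 6 higher ones in pituitary, at 37.3% against 5.39%. In testicle BBOF1, a protein of cilia, had 7 lower cytosines, at 38.8% ± 5.31 against 74.8%, and DCDC2C 3, at 10.4% ± 9.03 against 67.7%.

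The differences that set organs apart exceeded what random sign changes of the within-calf differences gave. Over 100 sign changes, the real one included, 1 gave as many calls for each organ, so random signs between calves did not give these counts. The test cannot tell an organ difference from a fixed offset of processing. Nor can it, for promoters, from one of the cytosines measured, since such offsets have the same sign in each calf. Called promoters were 11 in liver (highest other 6), 9 in muscle (1), 14 in hypothalamus (6), 9 in pituitary (5) and 11 in testicle (4). Called cytosines were 2626 in liver (12), 2756 in muscle (1), 2468 in hypothalamus (886), 5406 in pituitary (90) and 3479 in testicle (213). Adrenal promoters, as first planned, numbered 43 (highest other 39), also with 1 of 100. All 43 were higher in adrenal gland, and the other organs averaged 31.3% there.

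For IVP against MOET cytosines, chance could not be excluded in 5 organs by the 35 splits of the calves. As many were called in 3 splits in liver (165, highest other 601), 10 in muscle (317, 648), 6 in hypothalamus (235, 1347), 3 in pituitary (85, 660) and 5 in testicle (282, 1316). Where 0 were called, as for adrenal cytosines and for promoters of each of the 6 organs, 35 of 35 splits matched by construction, which decides nothing. The highest other split called 0 adrenal cytosines, and 2, 4, 2, 2, 2 and 1 promoters in liver, muscle, hypothalamus, pituitary, testicle and adrenal gland. Without MOET_3213 as many were called in 12 of 35 splits of 7 calves in liver (502, highest other 1411), 9 in muscle (1375, 3433), 14 in hypothalamus (688, 1926), 15 in pituitary (382, 1022) and 19 in testicle (666, 2349), and adrenal gland again had 0 in 35 of 35. In liver the 3 and 3 libraries without rescaled coverage gave 595 called cytosines, against 165 with all 8. The binomial test without spread called 12341 cytosines, and 7 splits called as many, up to 15316. Splits with several times the real count point to a structure of the samples. In liver, hypothalamus, pituitary and testicle the same split called the most. It set IVP_3208, IVP_3209, MOET_3217 and MOET_3218 against MOET_3213, IVP_5833, IVP_5841 and MOET_5932, and in muscle it called 0. In hypothalamus the median count was 189.5 in splits that kept MOET_3213 and MOET_5932 together and 0 in those that parted them, in testicle 198 and 0.5, but in muscle 0.5 and 156.

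Few cytosines such as those of COMMD7 and MTREX were called between IVP and MOET calves, and several explanations stay open. A missing direction between calves may contribute to low p values. By the quasi-likelihood test, simulated data without change had 7.52% of cytosines at a p under 0.05 with the direction missing and 5.48% with complete data. A simulated set had at most 2 calls with the direction missing and at most 1 with complete data, so added calls were not shown. The simulated calves held only a small random spread and no sequence variants. Limma on percentages called 119 cytosines in the 6 organs and 11 with that direction as covariate. Covariates that parted 11 other pairs of calves of 1 origin left 63 to 123, so the drop exceeded the cost of a covariate. The differences stayed as large, with medians at the limma calls of 56.4 and 56.9 points in liver, 50.2 and 50.5 in hypothalamus and 49.9 and 49.9 in testicle, while the standard errors grew. Haplotypes shared by calves of a group could also contribute, because the share of calls within 1000000 bp of another exceeded the highest random draw by at least 21.2 points in each organ with calls. An effect of embryo origin before the organs formed cannot be told apart from these, since called cytosines kept their direction in another organ in 99.6% of comparisons and other splits did so in 94.1% to 100%.

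Adrenal cytosines had nearly equal levels, in promoters and introns alike. An adjustment that removed the level of each cytosine may explain this, because the opposite-strand cytosines of a CpG had mean levels correlated at 0.058 in adrenal gland and at 0.954 to 0.963 in the other organs. Exchanged animals are argued against for 7 calves, since adrenal libraries correlated best with their own calf in 90% of 80 comparisons, and in 70 of 70 without MOET_3213. No biological explanation was tested.

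Differences between calves, such as those at RCAN2 and DHRS7B, recurred across organs, and a library correlated best with its own calf in 216 of 240 comparisons. All 24 misses were libraries of MOET_3213, and without it 210 of 210 matched. A batch shared by the libraries of a calf may contribute and stays open. Without suspected sequence variants at most 43.7% of the same-calf correlation was kept, under the bound of 50% set beforehand. That bound was wrong, because those cytosines were chosen by their spread between calves, so a drop follows from the choice. Variants at the CpG may explain part. The neighbouring CpG followed the calves with at most 0.498 of the correlation of the opposite strand. This ratio lay under the bound of 0.5 in each of 6 organs, and was 0.444 ± 0.0205 (SE) over the organs. Their calves and cytosines overlap. The upper limit of the ratio from its SE was 0.625 in liver, 0.604 in muscle, 0.589 in pituitary and 0.53 in adrenal gland. These limits exceed the bound, so the test cannot decide in these organs. The limit was 0.5 in hypothalamus and 0.447 in testicle. The reading of this test was changed after the values were seen. Parentage of the calves stays open and untested.

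The values of MOET_3213 did not follow 1 pattern across the organs. Between liver, hypothalamus, pituitary and testicle MOET_3213 correlated with itself at 0.171 to 0.262 and with MOET_5932 at 0.176 to 0.266. MOET_5932 correlated with itself at 0.185 to 0.272 there. Between these organs and muscle or adrenal gland MOET_3213 correlated with itself at -0.0156 to 0.0222 and MOET_5932 with itself at 0.0645 to 0.0825. The other calves had at least 0.0757 there. Between muscle and adrenal gland MOET_3213 correlated with itself at 0.126. Libraries exchanged with independent libraries of another calf are argued against, since the variance along the missing direction was at most 7.22% of the counting noise that independent libraries would have. Values computed in part from other libraries after counting may explain it, with the same 7.22%. The step itself is not recorded, and pairing by calf number rests on 7 calves.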
